A study of Mus musculus with 4 samples.

How the data were processed

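Kidney tubules came from transgenic mice in which the parvalbumin promoter drives the green fluorescent protein eGFP, per the labels. The reporter marks the distal convoluted tubule (DCT), the last nephron segment in which filtered magnesium is taken back up under control of the body's needs. The mice were fed a diet with 0.02% or 0.48% magnesium by weight for 15 days and were 6 to 8 weeks old when tubules were isolated. Per the labels' protocols, kidneys were digested with collagenase and hyaluronidase, fluorescent fragments were picked by a large-particle sorter, and the RNA of 4000 fragments was pooled, amplified as cRNA and coupled to Cy3 or Cy5.

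There were 8 RNA samples on 4 mouse arrays read in 2 colours. Each array held a low-diet and a high-diet sample of littermates, so the array was the pair and the unit of replication. Pairs are named by the sample numbers in the labels, H for high and L for low: H1/L1, H3/L2, H7/L7 and H8/L8. The low-diet sample was in Cy5 on H1/L1 and H7/L7, and the high-diet sample was in Cy5 on H3/L2 and H8/L8. Channel 1 of the scan was taken as Cy5, since the labels list Cy5 first. The labels do not say whether a sample came from 1 mouse or from several, so p-values refer to these 4 pairs.

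The deposited scan of each array gives intensities per spot on a linear scale, as mean and median pixel brightness of signal and local background, and they were not background subtracted. The scanner and the spot-finding software are not given in the sources used here. A deposited table of the authors' processed values holds a log2 ratio per spot and array, with channel 1 over channel 2 and no turn for the dye swap. Scale and direction were found by setting each column against its array's scan, with a correlation between 0.739 and 0.872 across brighter spots. Its medians were 0.0041 for H1/L1, -0.0038 for H3/L2, -0.0035 for H7/L7 and 0.0047 for H8/L8. Its normalization is not given in the sources used here, and 0 of 39429 probes in it had an unadjusted p under 0.05 for a dye effect, against 6618 in the ratios computed from the scans. Chance alone would give about 5%, so a dye effect per probe appears to have been removed from the deposited values, and a count of dye effects in them is not informative. A further deposited table, made with maanova per the file headers, holds the authors' mean log2 ratio and a p-value per probe. Whether that p-value was adjusted is not given in the sources used here, and 37011 of its values were exactly 1. Its log2 ratio ran high over low diet, with a Pearson r of -1 across probes against the mean of the turned processed values.

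From the scans, the mean pixel signal was corrected with normexp at an offset of 50, and log2 ratios were normalized within each array by loess with the 5791 control spots at weight 0. The scans held no column of spot flags. Ratios were turned to low over high diet. The model was fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with a term for diet and an intercept for the dye, moderated by eBayes, 2-sided, and adjusted by the Benjamini-Hochberg method at 0.05. This left 2 residual degrees of freedom per probe, to which the moderation added 2.68 prior degrees of freedom. The residual spread is that between pairs of the same dye orientation. A difference between the pairs of 1 orientation and those of the other counts as a dye effect and does not enter the p-values for diet. The mean and SD printed for a gene are over the 4 turned ratios, so the SD also holds the dye effect that the fit removes. Every adjusted p of a gene is limma's with Benjamini-Hochberg adjustment over 39429 probes, unless said otherwise.

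Of the 39429 probes, 32431 carried 1 gene symbol in the platform annotation, 6998 carried none here and 0 carried several. The 21713 distinct symbols were counted after 2622 old symbols had been updated through unique synonyms in the RefSeq gene table of assembly GRCm38.p6, and 33 symbols not found there were kept as given. No genome build is named by the files, so no coordinates are printed. A gene was represented by its probe with the highest mean brightness. A channel was called above background where the mean signal minus the median background exceeded the 99th percentile of a dim control probe with 604 spots, and a spot was called saturated at a median of 65000 or more. Each of the 58 named genes was measured above background in both diets and below saturation on at least 1 array. Of them Egf had a saturated spot, in the low-diet sample of H1/L1.

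Gene lists were tested with camera at a preset correlation of 0.01 between genes, with an estimated correlation beside it, and with fry, each adjusted over 26 lists. The named genes followed a rule set before the data were examined. It took the 12 genes with the largest positive and the 12 with the largest negative log2 ratio among those past the threshold with the same sign in all 4 pairs. It added every gene of the magnesium handling and follow-up lists with an unadjusted p under 0.05, together with Trpm6, Pvalb, Slc12a3, Slc41a3, Cnnm2 and Egf. It also took the 4 members with the largest moderated statistic of each other list that passed camera. Lists, model, rule and most alternatives were set before the data were examined. Other genes named in the text, all members of those lists, were chosen after their values were seen.

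The procedure was tested on simulated ratios for the comparison of diets over 39429 probes, with 100 probes changed by a log2 of 0.5 and 100 by 1. It recovered 73% and 99% of them, with 8 false among 180 calls. When each probe kept its own spread as moderated by eBayes, which draws it toward a common value, 13 of 208 calls (6.25%) were false. Of 100 unchanged lists of 20 genes, 2 had an unadjusted camera p under 0.05, as did all 100 lists shifted by a log2 of 0.2. Genes were simulated as independent of each other. The simulation therefore does not test camera where genes of a list move together, as the proximal tubule markers did (estimated correlation 0.777). The alternatives changed the dye term, background correction, normalization, filter on dim probes, pixel statistic, variance model, source of the ratios and probe per gene, or left out each pair. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.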

Results

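Transcript levels in sorted DCT fragments were compared between mice on a low and a high magnesium diet, on 4 arrays that each held a littermate pair. The series set out to find genes of this segment that take part in magnesium balance. Each array carried 45220 spots, and 39429 probes were tested. The low-diet sample was above background at 97.4% of probes on H1/L1, 81.1% on H3/L2, 95.02% on H7/L7 and 65.5% on H8/L8, and the high-diet sample at 85.1%, 92.6%, 85.7% and 96.2%. On each array the sample in Cy5 had the higher share, whichever diet it came from. Between 26 and 51 spots per array were saturated in Cy5. The number of arrays limited the precision.

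The first comparison asked which transcripts differed between the diets. All log2 ratios run low over high diet, opposite to the authors' deposited table, so a positive value is a higher level on the low-magnesium diet. Among the largest rises was that of Pvalb, which encodes the calcium-binding protein parvalbumin and whose promoter drove the reporter used for sorting, at a log2 ratio of 2.27 ± 0.40 (SD, n = 4; 4.81-fold; adjusted p = 0.0121), with a second, dimmer Pvalb probe at 1.41 ± 0.37. Sox9, a transcription factor active in tubule repair, rose by 2.13 ± 0.47 (4.39-fold), and Calb1, which encodes the calcium buffer calbindin-D28k, by 1.54 ± 0.41 (2.92-fold). Ptger3, which encodes the EP3 receptor for prostaglandin E2, fell, with a log2 ratio of -1.95 ± 0.35 (3.86-fold lower; adjusted p = 0.00985) by its brightest probe and of -0.39 ± 0.17 (adjusted p = 0.0358) by a dimmer probe. Each of these genes moved the same way in 4 of 4 pairs.

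The largest rises and falls were ranked among genes past the threshold by their brightest probe, with the same sign in all 4 pairs. The 12 genes with the largest rises also held Umod, which encodes uromodulin, at 1.46 ± 0.25, and Prkd1, which encodes protein kinase D1, at 1.57 ± 0.18 (SD, n = 4). Pck1, the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, rose by 1.55 ± 0.49, Gulo, the last enzyme of ascorbate synthesis, 2.83-fold (SD 0.29 on the log2 scale), and Ptgs1, which encodes cyclooxygenase-1, by 1.29 ± 0.18. Dnaja4, which encodes a co-chaperone of the heat shock proteins, rose by 1.67 ± 0.08. Cd55, which encodes an inhibitor of complement, rose by 1.59 ± 0.69, Plppr4 by 1.53 ± 0.44 and Ecrg4 by 1.23 ± 0.54. The 12 genes with the largest falls were Ptger3, Lrrn1 at -1.50 ± 0.39, Ndrg4 at -1.32 ± 0.32, Mreg at -1.30 ± 0.34, Kap at -1.22 ± 0.73, Ell3 at -1.10 ± 0.19, Tmed6 at -1.01 ± 0.22, Ckb at -0.98 ± 0.35, Nqo1 at -0.97 ± 0.42, Gm12892 at -0.97 ± 0.33, Gstt1 at -0.94 ± 0.16 and Pdpn at -0.92 ± 0.15. Kap, the kidney androgen-regulated protein, is made in the proximal tubule, and Ckb is the brain-type creatine kinase. Nqo1 and Gstt1 encode detoxifying enzymes. Of these 24 genes, 10 had several probes, and a dimmer probe missed the threshold for 6 of them (Dnaja4, Prkd1, Plppr4, Tmed6, Gstt1 and Pdpn). The dimmer probes had log2 ratios of 0.09 for Dnaja4, 0.02 for Prkd1 and -0.06 for Plppr4. Those of Tmed6, Gstt1 and Pdpn were at -0.27, -0.14 and -0.06. The dimmer Pdpn probe was above background on 1 array per diet, the others on all 4. The differences of these 6 genes thus rest on their brightest probe. Among all 58 genes named by the fixed rule, 27 had several probes, and these differed in the call for 17: the 6 above and Nipa2, Rac1, Tbc1d4, Hspa4l, Hsph1, Sdhb, Rpl24, Rps20, Rps2, Sc5d and Idi1.

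**Figure D1:**
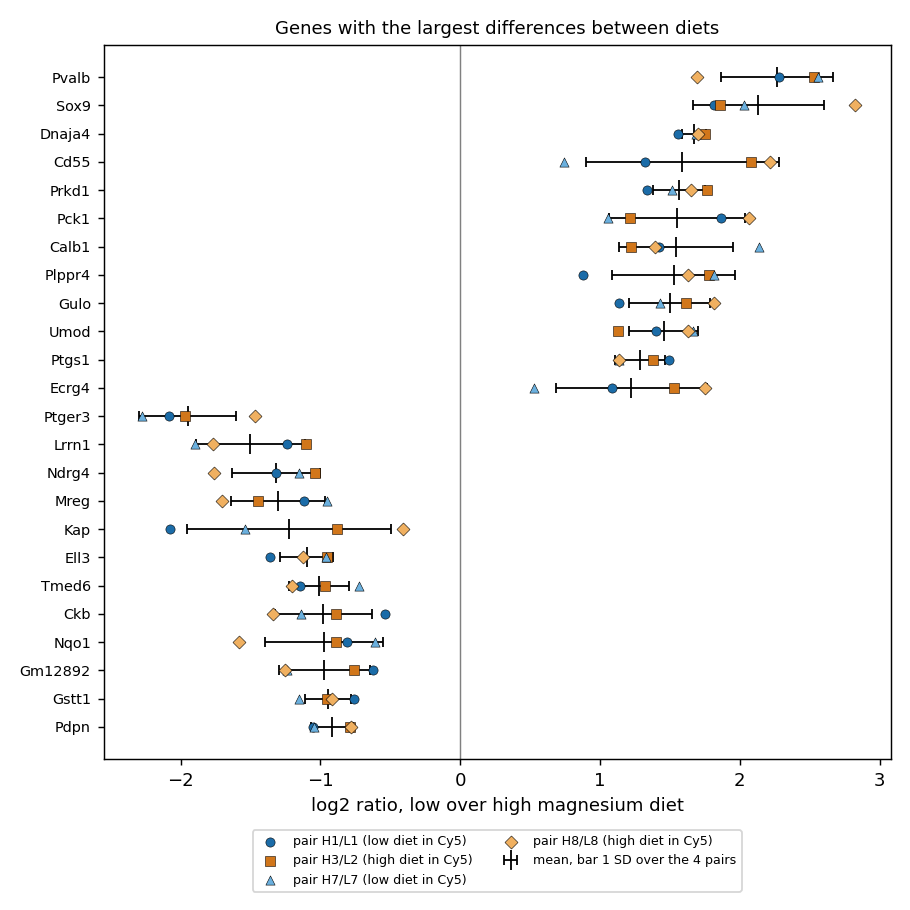
Log2 ratio of low over high magnesium diet (x axis) for the 12 genes with the largest rises and the 12 with the largest falls by their brightest probe (y axis). They were ranked among genes past the threshold with the same sign in all 4 pairs. Each gene has a point per pair and a bar of 1 SD around the mean of the 4 pairs. All points of a gene lie on the same side of 0, from 2.82 for Sox9 in H8/L8 to -2.28 for Ptger3 in H7/L7.

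In all, 2296 of the 39429 probes passed the threshold, 1371 higher and 925 lower on the low diet. By their brightest probe, 1699 named genes passed, 1059 higher and 640 lower. Of 41 probes with a change of 2-fold or more, 38 passed, 30 higher and 8 lower. Of the calls, 2168 had the same sign in all 4 pairs; among all probes 24.6% did. Independent signs would give 12.5%, but pairs of the same dye orientation share dye effects, so this is no exact chance level. The call count was 83 without pair H1/L1, 863 without H3/L2, 437 without H7/L7 and 225 without H8/L8, with 13, 20, 17 and 12 of the 24 genes above past the threshold. The direction of these genes could not turn there, since they were chosen for the same sign in all 4 pairs. It was 824 without the dye term (571 higher, 253 lower) and 279 with plain background subtraction (204 higher, 75 lower), and the share of higher calls moved from 59.7% to 73.1% in the latter.

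Magnesium handling was the process the series was about. Trpm6, the magnesium channel of the DCT's luminal membrane, rose by 1.01 ± 0.23 (SD, n = 4; 2.02-fold; adjusted p = 0.0180), in 4 of 4 pairs. Its relative Trpm7 rose by 0.42 ± 0.28, Cnnm2, a membrane protein in which mutations cause renal magnesium loss, by 0.71 ± 0.27, and Egf, the precursor of a hormone that stimulates magnesium uptake in this segment, by 0.71 ± 0.68. The Egf spot was saturated in the low-diet sample of H1/L1, so its ratio there is a lower limit and the mean is not exact. Nipa2 rose by 0.16 ± 0.17, with 3 of 4 pairs above 0. With Pvalb, 6 of 22 measured members of the list rose, and 1 fell, namely Rac1 at -0.26 ± 0.08. A second Rac1 probe of nearly the same brightness rose by 0.26 ± 0.28 (adjusted p = 0.0252), so the direction of this gene was not settled. Adjusted over the list alone, 6 members rose and 4 fell. As a group, the list did not shift in 1 direction against other genes (camera, adjusted p = 0.580), a test in which rises and falls offset each other. By their brightest probe 7 of the 22 members passed, against 1699 of 21713 named genes.

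Other members did not pass over all probes. Cnnm1 had a log2 ratio of -0.17 ± 0.31, Cnnm3 of 0.26 ± 0.21, Fxyd2 of -0.26 ± 0.58, Cldn19 of -0.28 ± 0.16 and Mrs2 of -0.35 ± 0.25, with adjusted p between 0.0935 and 0.223; of these, Cnnm1, Cldn19 and Mrs2 passed when adjusted over the list alone. The ratios of Trpm7 were 0.71 and 0.52 on H1/L1 and H7/L7 against 0.39 and 0.05 on H3/L2 and H8/L8, and those of Egf were 1.02 on H7/L7 and a lower limit of 1.53 on H1/L1 against 0.14 and 0.16. Of the 7 calls in the list, 0 remained without pair H1/L1, 2 without H3/L2 (Pvalb and Trpm6), 2 without H7/L7 (Pvalb and Egf) and 2 without H8/L8 (Pvalb and Trpm6); 4 remained without the dye term and 2, Pvalb and Trpm6, with plain background subtraction. The log2 ratios stayed at 79.7% to 120.3% of their size when a pair was left out, with Trpm6 at 1.00 without H1/L1 and 1.03 without H7/L7.

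The 4 genes taken further by the study rose together, but they had been chosen on these samples and are not independent evidence of a direction. Slc41a3, a relative of the magnesium transporter Slc41a1, rose by 0.84 ± 0.16 (SD, n = 4; adjusted p = 0.0146). Pcbd1, a co-factor of the transcription factor HNF1, rose by 1.08 ± 0.24, Tbc1d4, a regulator of the traffic of membrane proteins, by 1.10 ± 0.20, and Umod by 1.46 ± 0.25. All 4 rose in 4 of 4 pairs, and all 4 passed when adjusted over the list alone. A second, dimmer probe of Tbc1d4 had a log2 ratio of -0.05. The list passed camera (adjusted p = 2.32e-05) and fry (adjusted p = 0.0409), but not camera at adjusted p = 0.740 with an estimated correlation. Without pair H1/L1 only Pcbd1 stayed past the threshold, with log2 ratios of the 4 genes between 0.78 and 1.52, and without H8/L8 Pcbd1 did not pass. Slc12a3, the sodium chloride cotransporter by which the DCT is recognised, had a log2 ratio of 0.13 ± 0.27 (adjusted p = 0.467).

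**Figure D2:**
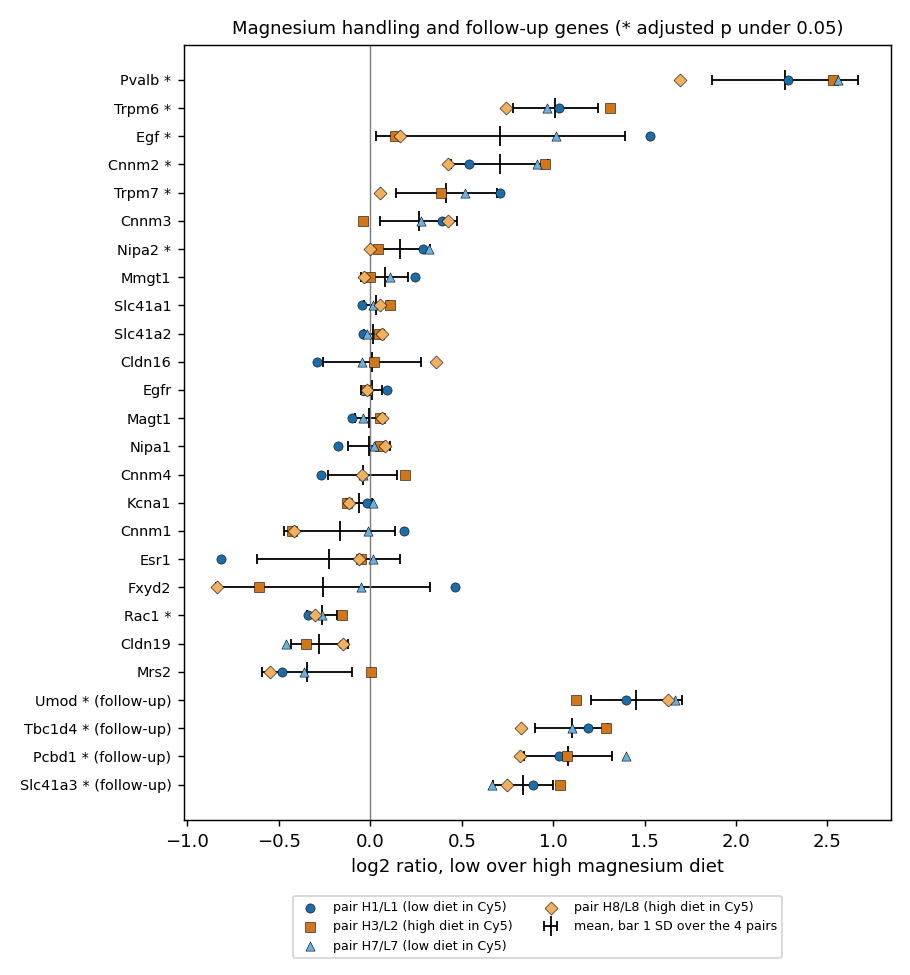
Log2 ratio of low over high magnesium diet (x axis) for the 22 measured magnesium handling genes and the 4 follow-up genes (y axis), with a point per pair and a bar of 1 SD around the mean of the 4 pairs; stars mark adjusted p under 0.05. Pvalb, Trpm6 and Cnnm2 lie above 0 in all 4 pairs, as do the 4 follow-up genes, and so do Trpm7 and Egf, whose lowest points are 0.05 and 0.14; the Egf point of H1/L1 is a lower limit because of saturation.

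Calcium handling genes included several of the clearer changes. Calb1 rose by 1.54 ± 0.41, Vdr, the vitamin D receptor, by 1.04 ± 0.13, Kl, which encodes the FGF23 co-receptor klotho, by 0.88 ± 0.16, and Pth1r, the parathyroid hormone receptor, by 0.76 ± 0.27 (SD, n = 4). Casr, the calcium-sensing receptor, had a log2 ratio of -0.75 ± 0.28 and fell in 4 of 4 pairs. Of 15 measured members, 4 rose and 1 fell, and adjusted over the list alone 4 rose and 3 fell (camera, adjusted p = 0.554). The calcium channel Trpv5 had a log2 ratio of -0.11 ± 0.18. S100g, the calbindin-D9k gene, had 2 probes with log2 ratios of -1.07 ± 1.11 (adjusted p = 0.0607) and -1.10 ± 0.94 (adjusted p = 0.0456), both below 0 in 4 of 4 pairs. The ratios of the first probe were -0.26 on H1/L1 and -0.17 on H7/L7 against -2.55 on H3/L2 and -1.30 on H8/L8. Among 19 measured genes of sodium chloride and potassium transport, the kinase Wnk1 rose by 0.67 ± 0.48 and the ubiquitin ligase Nedd4l by 0.34 ± 0.16, and the kinase Sgk1 fell by 0.75 on the log2 scale (SD 0.45). The 16 others did not pass; adjusted over the list alone 5 rose and 3 fell (camera, adjusted p = 0.526).

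The next comparison asked whether genes of other nephron segments and cell types, or of general cell functions, moved as groups. Of 26 lists, 6 passed camera at the preset correlation, 2 higher and 4 lower on the low diet. With an estimated correlation 0 passed, and 1 list had an unadjusted p under 0.05. The follow-up genes, which had been chosen on these samples, were 1 of the 2 higher lists. They were also the list with that unadjusted p and the only list past fry, so neither count is independent evidence. Heat shock genes rose, with 6 of 15 members up, 0 down and a median log2 ratio of 0.21 (camera, adjusted p = 1.53e-04; adjusted p = 0.740 with an estimated correlation). Hsph1 rose by 0.62 ± 0.22, Hspa4l by 0.58 ± 0.08, Dnajb1 by 0.44 ± 0.18 and the mitochondrial chaperonin Hspd1 by 0.33 ± 0.09 (SD, n = 4). When adjusted over the list alone, 9 rose and 0 fell.

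Genes of oxidative phosphorylation, the respiratory chain and ATP synthase of mitochondria, fell, with 27 of 93 members down, 0 up and a median log2 ratio of -0.22 (camera, adjusted p = 3.96e-17; adjusted p = 0.922 with an estimated correlation). A spot was saturated on at least 1 array for 3 of the 93 members. The list median was -0.11 in H1/L1, -0.12 in H3/L2, -0.20 in H7/L7 and -0.34 in H8/L8. Sdhb of complex II had a log2 ratio of -0.55 ± 0.13, Cox5b of complex IV of -0.55 ± 0.13, and Ndufv2 and Ndufb9 of complex I of -0.52 ± 0.15 and -0.38 ± 0.19 (SD, n = 4). Adjusted over the list alone, 51 fell and 0 rose.

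Proximal tubule markers fell as a group, with a median of -0.32 (camera, adjusted p = 0.00272; adjusted p = 0.922 with an estimated correlation), but their medians were -0.94 in H1/L1, -0.40 in H3/L2, -0.04 in H7/L7 and 0.07 in H8/L8. Of 25 members, Kap and the glucose transporter Slc5a2 (-0.88 ± 0.37) fell and Ggt1 rose by 0.22 ± 0.17 (SD, n = 4), the same counts as adjusted over the list alone, and Slc5a12 had a log2 ratio of -0.72 ± 0.47 (adjusted p = 0.106). The list did not pass without pair H1/L1 (median -0.09, adjusted p = 0.0531) or without H3/L2 (median -0.17, adjusted p = 0.193), and its median was -0.64 without H7/L7. In H7/L7 and H8/L8 alone its median was -0.04 (adjusted p = 0.464). These pair medians stood beside those of oxidative phosphorylation, which were lowest in H7/L7 and H8/L8.

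Cytosolic ribosomal proteins fell, with 10 of 68 members down, 1 up and a median of -0.15 (camera, adjusted p = 4.27e-10; adjusted p = 0.750 with an estimated correlation). Rpl24 had a log2 ratio of -0.42 ± 0.38, Rpl36 of -0.38 ± 0.31 and Rps20 of -0.31 ± 0.23 (SD, n = 4), and Rps2 rose by 0.23 ± 0.07. The list medians were -0.26 and -0.28 on H1/L1 and H7/L7 and -0.08 and 0.07 on H3/L2 and H8/L8. In the ribosomal list, adjusted over the list alone, 26 fell and 3 rose. Genes of cholesterol synthesis fell, with 4 of 17 members down, 1 up and a median of -0.09 (camera, adjusted p = 0.0232; adjusted p = 0.922 with an estimated correlation). The squalene epoxidase gene Sqle had a log2 ratio of -0.88 ± 0.42, Idi1 of -0.84 ± 0.43 and Fdps of -0.43 ± 0.07, and Sc5d rose by 0.38 ± 0.32 by its brightest probe, while a dimmer Sc5d probe had a log2 ratio of -0.20 (adjusted p = 0.106). Adjusted over the list alone, 7 fell and 2 rose, and the list did not pass without H3/L2 (median -0.03, adjusted p = 0.209), while its median was -0.04 without H1/L1 (adjusted p = 0.0499). It also did not pass with the dimmest 50% of probes left out (adjusted p = 0.0629), with the mean of a gene's probes (adjusted p = 0.0641) or in H7/L7 and H8/L8 alone (adjusted p = 0.104).

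Of the 10 thick ascending limb markers, which include Umod and 2 more genes held by another list, Umod and the potassium channel Kcnj1 (0.66 ± 0.57) rose and Ptger3 fell, while the cotransporter Slc12a1 had a log2 ratio of 0.17 ± 0.31 (SD, n = 4; adjusted p = 0.205). Adjusted over the list alone, 3 rose and 2 fell (camera, adjusted p = 0.835). Of 13 principal cell markers, the transcription factor Tfcp2l1 rose by 0.53 ± 0.23, and adjusted over the list alone 1 rose and 1 fell (camera, adjusted p = 0.861). Avpr2, the vasopressin V2 receptor, also passed as lower, but its spot was saturated in 1 low-diet and 2 high-diet samples, so its direction is not settled and no ratio is given. None of 76 markers of intercalated cells, podocytes, endothelium, stroma, leukocytes and red blood cells passed in limma, and 12 of them had an unadjusted p under 0.05; adjusted over the list alone the count was 0 as well. The medians of these 6 lists lay between -0.07 for endothelium and 0.04 for intercalated cells, with camera's adjusted p between 0.289 and 0.960. Median and mean lay above 0 but camera's direction was lower for principal cells, intercalated cells and immediate early genes; for stroma and for the interferon response the median lay above 0 and the mean below it.

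**Figure D3:**
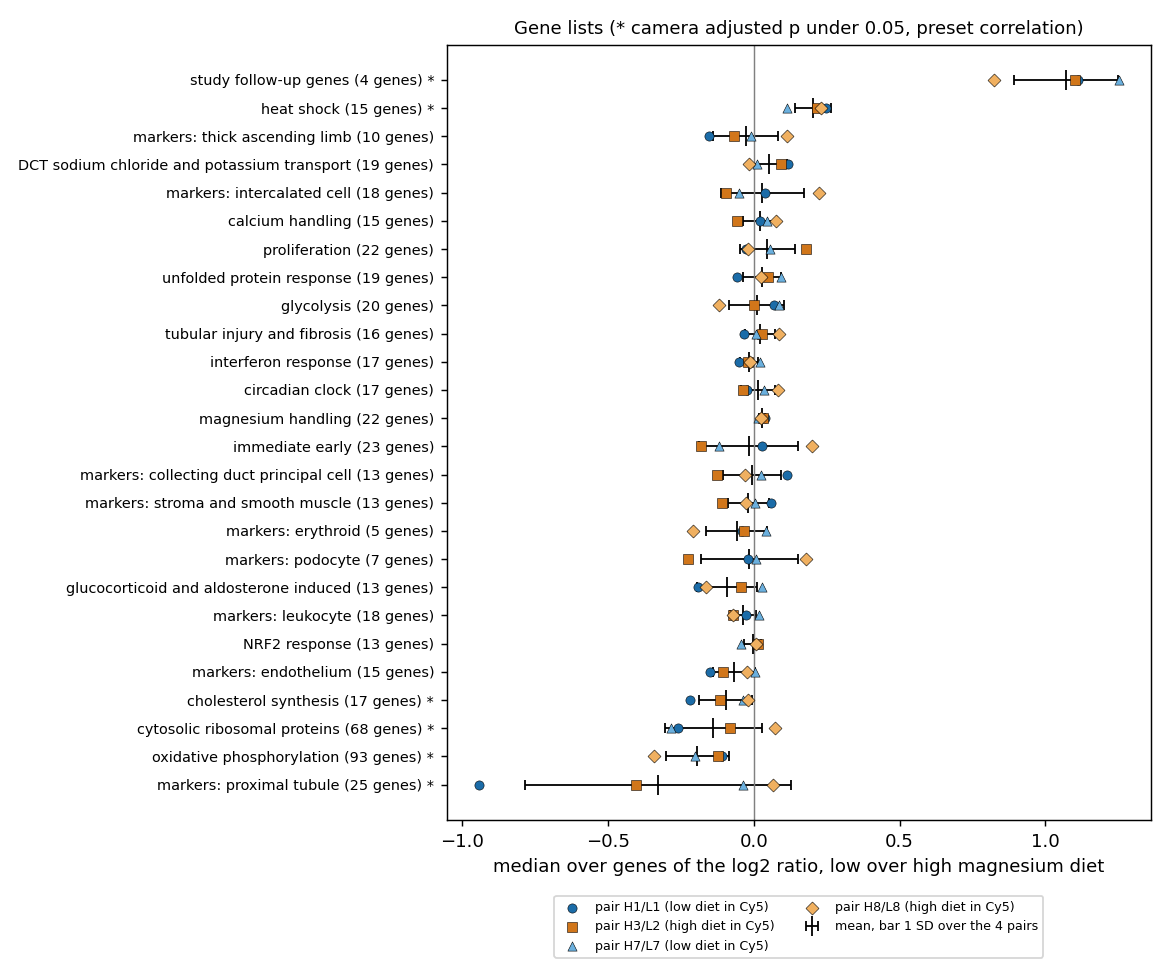
Median over genes of the log2 ratio of low over high magnesium diet (x axis) for 26 gene lists (y axis), with a point per pair and a bar of 1 SD around the mean of the 4 pair medians; stars mark lists past camera's threshold at the preset correlation. The follow-up genes lie highest, at 0.82 to 1.25, and the proximal tubule markers spread most, from -0.94 to 0.07.

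The dye swap was used to see how much of each ratio came from the dyes. In limma, 2 probes had a dye effect past the adjusted threshold and 6618 an unadjusted p under 0.05, against 8489 for the diet. These counts cannot tell a dye effect from a difference between the littermate pairs of the 2 orientations. Across probes, the turned ratios of pairs with the same dye orientation correlated at r = 0.629 (H1/L1 with H7/L7) and 0.535 (H3/L2 with H8/L8). Pairs of opposite orientation correlated at r between 0.0640 for H1/L1 with H8/L8 and 0.320 for H3/L2 with H7/L7, with a mean of 0.195. Genes are not independent replicates, so these correlations carry no p.

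The authors' deposited table was set against these results. It listed 287 probes with a p under 0.05, of which 207 were higher and 80 lower on the low diet. Of these 287, 285 passed here as well, and 0 had the opposite direction. In the authors' deposited table, Pvalb had a log2 ratio of high over low diet of -2.33, Trpm6 of -1.04 and Ptger3 of 2.12. Across probes the log2 ratios of the authors' deposited table and those computed here had a Spearman correlation of -0.940 and a Pearson correlation of -0.980, with genes not independent and both made from the same arrays. Of the 287 probes, 59 passed without pair H1/L1 and 141 without H8/L8.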

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

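The tests of other diet assignments, of fragment amounts, of the background settings for the proximal tubule markers and of the marker transporters were chosen after the result was seen; the matched random lists and the settings for Pvalb, Trpm6, Slc41a3 and Umod were set before. In 91 sets of 4 values, covering the named genes, the lists and 7 measures of the arrays, 3 had a pair whose gap to its nearest neighbour was larger, as a share of the range, than Dixon's 95% critical value, which chance exceeds in about 5% of sets. Hsph1 had a log2 ratio of 0.95 in H1/L1 and 0.47 to 0.53 in the other pairs. The NRF2 response list had a median of -0.046 in H7/L7 and 0.0072 to 0.015 in the others. The dim control probe had a median net signal of 34.5 in Cy3 of H8/L8 and 8.12 to 8.57 in Cy3 of the other arrays. The background threshold was set from this probe, so the low share of low-diet probes above background on H8/L8, 65.5%, is no separate observation. The median net signal over gene probes was 72.0 in that channel, against 39.8 to 46.4 in Cy3 of the other arrays.

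The count of 2296 probes was set against other assignments of diet to the channels of the 4 arrays. Of 7 assignments that could be fitted with the dye term, 1, the real one, gave as many, and the highest other gave 54. With 7 assignments the share cannot fall below 0.05, so this count does not settle whether chance gave the calls.

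The median of the proximal tubule markers was below 0 in H1/L1 and H3/L2 and near 0 in H7/L7 and H8/L8. None of the 25 genes is held by another list, and the sort for fluorescent fragments would remove those of the proximal tubule. Background correction or normalization of dim spots is argued against, since the list median nearest 0 under 7 other settings, of which 1 scales brightness and leaves ratios as they are, was -0.28. The markers deviated together from pair to pair, with an estimated residual correlation of 0.777, but a different amount of proximal tubule fragments in some sorts and a response to the diet in some litters would both give this and cannot be told apart; the 3 brightest markers, Slc27a2 (-0.25), Fbp1 (-0.42) and Cyp4b1 (-0.22), lay below 0 without passing the test.

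The median of the oxidative phosphorylation genes was below 0 in each pair, while 12 of the 93 members had a mean log2 ratio above 0. A loss of proximal tubule fragments as the whole cause was set against H7/L7 and H8/L8, whose proximal tubule interval reached 0. In both the 95% bootstrap interval over genes of this list lay below 0, with a highest upper bound of -0.13. In H8/L8 it lay below the proximal tubule interval (-0.41 to -0.30 against -0.28 to 0.14), which argues against that cause there. In H7/L7 the intervals overlapped (-0.28 to -0.13 and -0.15 to 0.06), so that pair does not decide. The bootstrap takes genes as independent, so its intervals can be too narrow. For a shift of all genes of similar brightness, 0 percent of 10000 random lists matched on brightness had a median as low, the lowest being -0.16. Loess had already centred the ratios along brightness on each array, so such lists lie near 0 largely by construction. The result shows only that genes of similar brightness kept no shift of this size after loess. Neither test covers the spread between pairs, over which the list did not pass with an estimated correlation. A response of these genes to the diet itself was not tested and stays open.

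Pvalb, Trpm6, Slc41a3 and Umod were higher on the low diet, and the sort selected on the promoter of Pvalb. A larger share of DCT material as the whole cause is argued against by Slc12a3. Its upper 95% bound of 0.35 lay below the 0.84 of Slc41a3 and the larger log2 ratios of the other 3 genes. This takes Slc12a3 itself as unchanged by the diet, which was not tested. More thick ascending limb material as the whole cause of the Umod difference is argued against by Slc12a1, with an upper bound of 0.33 against 1.46 for Umod. It too is taken as unchanged by the diet. The 95% interval of Slc12a1, 0.01 to 0.33, lay above 0, so such material as a part of the cause is not excluded. Of the 10 markers of that segment 6 lay above 0 and 4 below, with Kcnj1 at 0.66 and Ptger3 at -1.95. Under 7 other background and normalization settings each of the 4 genes kept at least 93.7% of its log2 ratio, which argues against these steps, while that of Slc41a3 ranged from 0.84 to 1.26. A response of these genes to the diet within the DCT and a sort that favoured brighter tubules on 1 diet were not tested and stay open.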

How the results depend on the processing

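The pairs H7/L7 and H8/L8 alone without the dye term, and the count of same-sign calls (2168), were chosen after seeing the data. No named gene that passed changed direction under 17 alternatives. For genes chosen for the same sign in all 4 pairs this is no test where pairs are left out. For all genes it is no test without the dye term, with brightness scaled between arrays, with dim probes left out or with trended robust variance. Those settings leave the mean log2 ratio of a probe as it is and can change only its p-value. Across 986 values of 58 named genes, 226 lost and 5 gained the call. Slc12a3, which had not passed, had the opposite sign (-0.04) in H7/L7 and H8/L8 alone. For 26 lists, 469 of 493 values kept their side of the threshold, 18 lost and 5 gained the call, and 1 was reversed. A turn of direction counted as kept where the list passed in neither setting. Calls numbered 824 without the dye term, 279 with plain subtraction, 83 to 863 when a pair was left out, and 0 (3158 at an unadjusted p under 0.05) in H7/L7 and H8/L8 alone, where both 2 pairs and the dye term were dropped. Magnesium handling calls fell from 7 to 4 without the dye term, 2 with plain subtraction, 0 to 3 without a pair and 0 in H7/L7 and H8/L8 alone. Of the authors' 287 probes, 59 to 230 passed without a pair and 0 in H7/L7 and H8/L8 alone. Lists past the threshold numbered 0 with an estimated correlation and 1 with fry, the follow-up genes chosen on these samples. They numbered 9 without H8/L8, 3 higher and 6 lower. In H7/L7 and H8/L8 alone, 4 were higher and 2 lower, against 2 higher and 4 lower with all pairs. Dye effects numbered 13 with an offset of 16, 13 with median pixels, 0 with plain subtraction, with trended robust variance and with the authors' processed values (where a dye effect appears to have been removed), 29680 with median centring alone, and 0 to 77 without a pair. Median centring turned the mean correlation of opposite orientations to -0.64, because it leaves the dye trend that loess removes. The intercalated cell list, with medians of -0.11 to 0.14 without a pair, passed as higher without H3/L2. Except for centring, the cause was not tested. The share of higher calls was 78.3% without H1/L1 and 80.0% without H8/L8. Print-tip loess (1 print block), flagged spots and slide batches were not run, since the scans give none. Each array was a littermate pair, so no further block was fitted. Signal over background limits low-diet values on H8/L8.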

Other observations

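The count over assignments without the dye term was chosen after the result was seen, as were the genes named in this part other than Sox9 and Nqo1.

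Genes of tubular injury and repair moved in part. Besides Sox9, the keratin gene Krt8 rose by 0.50 ± 0.09 (SD, n = 4), Spp1, which encodes osteopontin, by 0.63 ± 0.22 and Cd44 by 0.17 ± 0.18, the latter with 3 of 4 pairs above 0. The other 12 of 16 measured members did not pass, among them the injury markers Havcr1 (-0.03 ± 0.03) and Lcn2 (0.01 ± 0.11), and adjusted over the list alone 5 rose and 0 fell (camera, adjusted p = 0.403). Among 13 genes induced by glucocorticoids and aldosterone, Tsc22d3 rose by 0.66 ± 0.16 while Sgk1 fell by 0.75 on the log2 scale; adjusted over the list alone, 3 rose and 6 fell (camera, adjusted p = 0.593). In glycolysis, Pdk1, the kinase that holds back pyruvate dehydrogenase, rose by 0.57 ± 0.11 and the enzyme gene Tpi1 fell by 0.32 on the log2 scale, 2 of 20 members; adjusted over the list alone 4 rose and 2 fell (camera, adjusted p = 0.861).

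Single members passed in several more lists whose camera test did not. Of the unfolded protein response, Xbp1 (0.24 ± 0.08) and Asns (0.35 ± 0.27) rose, 2 of 19 (SD, n = 4), and adjusted over the list alone 4 rose and 0 fell (camera, adjusted p = 0.526). Ifit3 fell by 0.74 on the log2 scale as the single call among 17 interferon response genes, Nqo1 was the single call among 13 NRF2 response genes, Mcm7 fell by 0.28 as the single call among 22 proliferation genes, and Fosb fell by 0.18 as the single call among 23 immediate early genes. Adjusted over the list alone, 0 rose and 1 fell among interferon response genes (camera, adjusted p = 0.861), 1 rose and 1 fell among NRF2 response genes (adjusted p = 0.835), 2 rose and 1 fell among proliferation genes (adjusted p = 0.479) and 0 rose and 1 fell among immediate early genes (adjusted p = 0.580). None of 17 circadian clock genes passed in limma, 4 had an unadjusted p under 0.05, and 0 passed when adjusted over the list alone (camera, adjusted p = 0.861).

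Without the dye term, 8 assignments of diet to the channels could be fitted, and the real one gave 824 calls against 0 for the highest other. With 8 assignments the share cannot fall below 0.05 either, so this count does not settle whether chance gave the calls.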
